A study of Homo sapiens with 45 samples.

How the data were processed

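RNA was sequenced from 45 subcutaneous tumours of MIA PaCa-2, a human pancreatic ductal adenocarcinoma cell line, grown in NMRI mice. Each library therefore held transcripts of human tumour cells and of mouse host cells. Per the labels, tumours were left untreated (CTL) or received 10 Gy at 8 Gy per min from 6 MV photons (RT) or 25 MeV protons (PT). The letter G marks gemcitabine, a nucleoside analogue that blocks DNA synthesis, given at 40 mg per kg 24 h before irradiation. The letter O marks olaparib, an inhibitor of poly(ADP-ribose) polymerase, given at 50 mg per kg 1 h before irradiation. Irradiated tumours were taken 24 h after irradiation, and libraries were made from 400 ng of total RNA with a stranded dUTP protocol, per the labels.

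The deposited table holds raw counts per Ensembl gene for 58299 human and 54109 mouse genes, with human and mouse genes marked by their genome build, per the file headers. The counts were whole numbers and had not been normalised. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.3a and HTSeq 0.6.1p1 and the builds hg38 and mm10, without parameters. How reads matching both species were assigned, the annotation release and the strand setting of the counting are not given in the sources used here. Reads misassigned between the species would move counts between the human and mouse parts, and unstranded counting would mix a gene with its antisense partner. Histone, HLA and ribosomal protein genes have near-identical copies, so their counts are uncertain where reads could be shared. Of the human gene IDs, 58179 (99.8%) were found in the GENCODE v29 annotation of GRCh38, from which symbols, coordinates and transcript GC content were taken. Neither the table nor the reference pairs mouse gene IDs with names, so the 18 mouse gene lists fixed in advance could not be used.

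The human and the mouse part were analysed separately, each with its own library totals. Counts from a library with PCR duplicates are not independent molecules, so counting error understates the real error. Chi-square values per degree of freedom for 91 pairs of tumours in the same group ranged from 12.7 to 980, so variation between tumours exceeded counting error in every pair. The labels do not say which tumours came from separate mice, and p-values therefore measure only the spread between these tumours.

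In R 4.3.3, edgeR 4.0.16 was run with TMM scaling, its expression filter at a minimum count of 10, 1 coefficient per group and quasi-likelihood F tests. The Benjamini-Hochberg adjustment was applied within each comparison, and genes with an adjusted p under 0.05 were called changed. This left 17468 human and 15895 mouse genes, with biological coefficients of variation of 49.9% and 54.9%. There were 20 human and 11 mouse comparisons. They set each irradiated group against CTL, averaged the gemcitabine effect over its 4 pairs of groups, averaged the olaparib effect over its 4 pairs, averaged protons minus photons over 4 pairs, and compared single pairs of groups and their interactions with the beam. CPM values use TMM-scaled human library sizes, and log2 CPM used a prior count of 2.

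Human gene lists (18) were fixed from textbook knowledge. They covered p53 targets, S phase and replication, G2 and mitosis, homologous recombination and Fanconi genes, PARP, base excision and end joining, interferon response, antigen presentation, inflammatory and NF-kB genes, apoptosis, hypoxia, unfolded protein response, heat shock, cholesterol synthesis, EMT and TGF-beta, gemcitabine transport and metabolism, histone genes and ribosomal proteins, each tested with camera in limma 3.58.1. Camera used a preset correlation of 0.01 and was repeated with a correlation estimated from the data. The list of mitochondrially encoded genes had no member among the genes tested and was not analysed here. Genes named in the text came from the 8 rising and 8 falling called genes with the largest fold change and a mean log2 CPM of at least 1, and the 3 members with the smallest p of each called list and of the p53, S phase, mitosis, interferon and inflammatory lists. Some of these genes are not reported here. Outside the main comparisons at most 3 genes were named. Groups, comparisons, tests, lists and this naming rule were all set before the data were examined.

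The mouse share of counts was compared between groups with two-sided exact permutation tests in 12 comparisons. Tumour titles carry 1 of 4 prefixes (P3, P11, P6, P10) whose meaning is not given in the sources used here. P3 and P11 occur only in CTL and photon groups and P6 and P10 only in proton groups. Alternative settings, also set beforehand, were DESeq2 1.42.0, RLE factors, no expression filter, limma voom with quality weights, the prefix as a block, the log2 mouse to human count ratio as a covariate, a fit of only the groups compared, and leaving out each tumour in turn. A trend with transcript GC content was then seen between libraries. The GC slope of each library was computed over 11723 genes with a mean log2 CPM of at least 1, as the change in log2 CPM per 10 percentage points of GC. Fits with this slope as a covariate, the same with the prefix block, and fits without the 8 libraries whose slope exceeded 0.8 in size were chosen after seeing the data.

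The tests were tried on counts simulated from a negative binomial model with known changes, with a single data set per comparison. Its mean levels, dispersions and GC trend were estimated from these libraries. For RT against CTL, edgeR called 18% of genes changed 2-fold and 55% of those changed 4-fold, with 1 false call. For the gemcitabine average it called 65% and 91%, with 3 false calls. For protons minus photons it called 68% and 93% with 118 false calls, against 10 false calls with the GC slope as a covariate, 3789 with DESeq2 and 10157 with voom.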

Results

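The 45 tumours fell into 9 groups. There were 5 untreated tumours (CTL), 5 given photons (RT), 5 given gemcitabine and photons (RTG), 6 given olaparib and photons (RTO) and 5 given both drugs and photons (RTOG). Protons were given alone to 5 tumours (PT), with gemcitabine to 5 (PTG), with olaparib to 5 (PTO) and with both drugs to 4 (PTOG). No group received a drug without irradiation, so the effects of gemcitabine and olaparib were measured only among irradiated tumours. Total counts per tumour ranged from 17600847 to 52971045, of which 14204130 to 45369316 were human and 2222896 to 14358667 mouse. In the text, edgeR adjusted p is the quasi-likelihood p with Benjamini-Hochberg adjustment, log2 changes of genes are given ± their standard error, and CPM values are group means ± SD.

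Mouse genes, which report on the host cells in the tumour, made up 24.3% ± 5.64 of the counts in CTL (SD, n = 5), 24.9% ± 7.09 in RT (n = 5) and 24.4% ± 8.54 in PT (n = 5). The mean shares were 18.2% ± 4.41 in RTG (n = 5), 19.7% ± 3.49 in PTG (n = 5) and 19.0% ± 5.10 in PTOG (n = 4), and 26.6% ± 13.7 in RTOG (n = 5). RTO had 25.7% ± 9.68 (n = 6) and PTO 23.9% ± 7.95 (n = 5). None of the 12 differences tested exceeded the spread between tumours. The smallest p was 0.0952 for RTG against CTL, a difference of -6.08 percentage points (two-sided exact permutation test, Benjamini-Hochberg adjusted p = 0.57). The share followed the title prefix more closely than the treatment: within groups it was 14 points higher in P11 than in P3 tumours (permutation p = 1e-04, the smallest that 10000 permutations can give). Between P11 and P3 tumours 686 human and 663 mouse genes differed by edgeR with the treatment group in the fit, and between P10 and P6 tumours 0 of either.

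**Figure D1:**
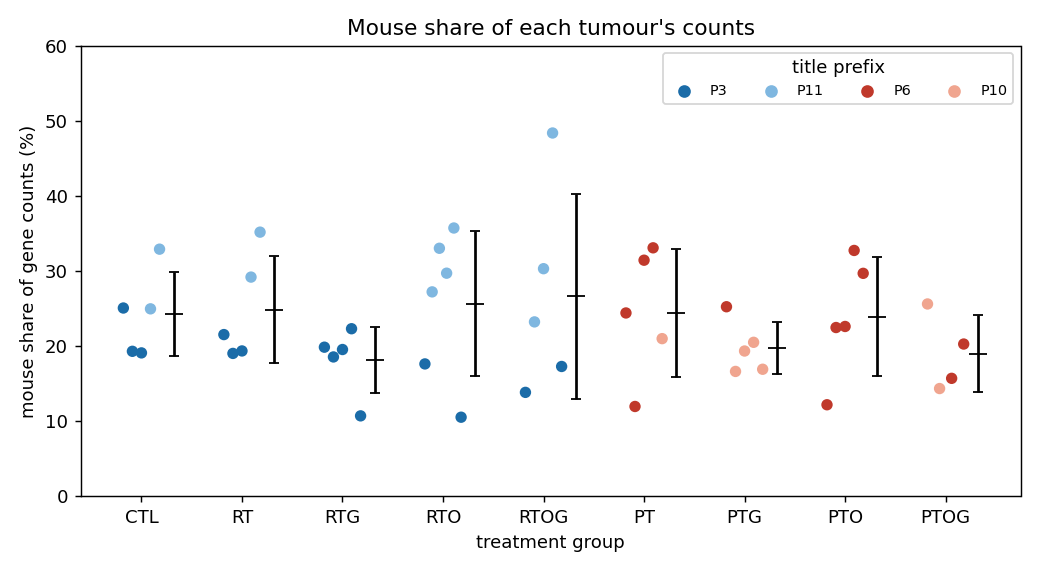
Mouse share of all counts in each of the 45 tumours by treatment group, in percent, with the group mean and SD. The group means lie between 18.2% and 26.6%, and the groups overlap.

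Human libraries also differed in how their counts followed transcript GC content. The slope of log2 CPM per 10 percentage points of GC ranged from -1.18 to 1.28 between tumours. It was 0.371 ± 0.218 in CTL (SD, n = 5), 0.38 ± 0.336 in RT (n = 5), -0.133 ± 0.976 in PT (n = 5) and -0.491 ± 0.498 in PTO (n = 5). Treatment group accounted for 26.5% of its variance (permutation p = 0.151). The slope was lower in the 19 proton tumours (-0.281 ± 0.601) than in the 21 irradiated photon tumours (0.166 ± 0.506), a difference of -0.447 (two-sided permutation test, p = 0.0156). The beams share no title prefix, so prefix and beam cannot be separated for this slope. Gene groups that moved between protons and photons are therefore given below with and without the slope as a covariate.

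**Figure D2:**
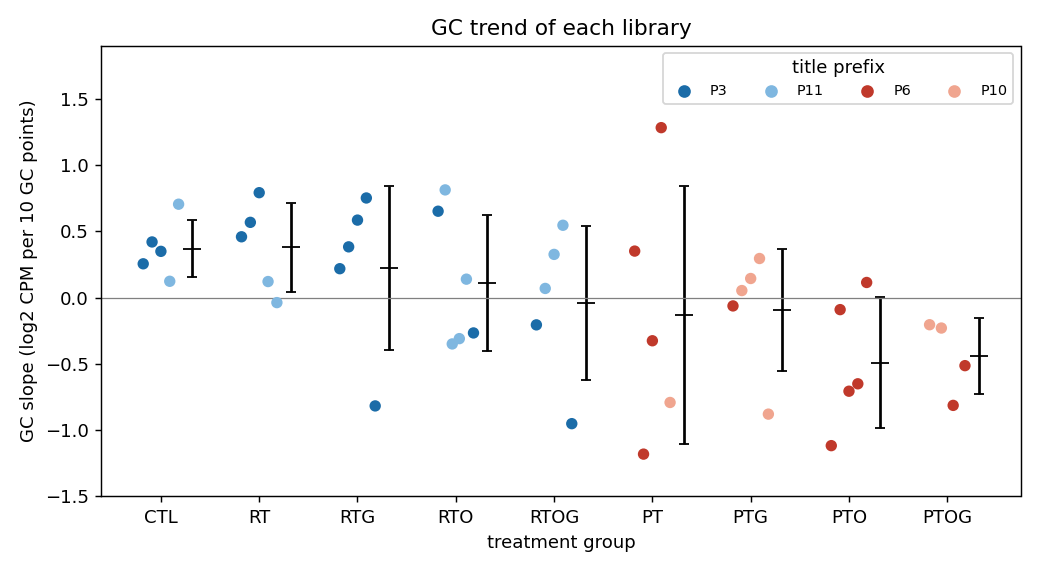
Slope of log2 CPM per 10 percentage points of transcript GC for each of the 45 human libraries by treatment group, marked by title prefix, with the group mean and SD. Slopes run from -1.18 to 1.28, and both ends of this range are in the PT group.

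Gemcitabine raised genes of DNA replication and of the interferon response in irradiated tumours and lowered genes of mitosis. CCNE2, a cyclin that drives entry into S phase, stood at 26.5 ± 6.77 CPM in RT (n = 5) and 83.2 ± 28.6 in RTG (n = 5), and at 59.7 ± 23.7 in PTO (n = 5) and 170 ± 38 in PTOG (n = 4). AURKA, a kinase of the mitotic spindle, stood at 252 ± 32.5 CPM in RT and 113 ± 19.2 in RTG, against 162 ± 19.2 in CTL, and at 151 ± 30.5 in PTO and 107 ± 13.6 in PTOG. OAS2, an interferon-induced enzyme activated by double-stranded RNA, stood at 16.5 ± 4.23 CPM in RT and 53.5 ± 28.4 in RTG, against 24.9 ± 5.64 in CTL. LINC00525 separated the treatments completely, with 22.3 to 63.4 CPM in the 19 tumours given gemcitabine and 5.08 to 20.5 CPM in the 21 irradiated without it. LINC00525 is annotated as antisense, and its reads are uncertain because the strand setting of the counting is not known. CCNE1, the other cyclin E, ranged from 28.3 to 62 CPM with gemcitabine and from 16.7 to 31.2 CPM without.

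Averaged over the 4 pairs of groups that differ in gemcitabine, edgeR called 759 of 17468 human genes, 473 higher and 286 lower. CCNE2 (chromosome 8, 94879770 to 94896678, GRCh38) rose by 1.61 ± 0.19 on the log2 scale (edgeR adjusted p = 1.06e-07). VDR, the vitamin D receptor, rose by 1.77 ± 0.22 (edgeR adjusted p = 5.69e-07) and HSD17B6, a steroid dehydrogenase, by 1.51 ± 0.19 (edgeR adjusted p = 9.3e-07). RHBDL3 rose by 1.80 ± 0.26, the noncoding LINC01629 by 1.77 ± 0.29 and LINC00525 by 1.73 ± 0.12, with edgeR adjusted p between 4.51e-13 and 7.8e-05. Among falling genes, the change was -1.54 ± 0.25 for PIF1, a DNA helicase (edgeR adjusted p = 5.8e-05), -1.22 ± 0.29 for CDC20, an activator of the anaphase-promoting complex (edgeR adjusted p = 0.00781), and -1.17 ± 0.25 for PLK1, a mitotic kinase (edgeR adjusted p = 0.00234). TSPAN18 (-1.36), MEDAG (-1.17) and the microtubule-linking GAS2L3 (-1.08) fell as well. SUN2 (-1.33, edgeR adjusted p = 0.0255) and LAG3 (-1.22, edgeR adjusted p = 0.0301) lost the call with the title prefix as a block (0.286 and 0.366), as did IFI27, a rising interferon gene (log2 change 1.51, adjusted p = 0.057 with the block). With the GC slope as a covariate 3376 genes were called, including all 759, and with the title prefix as a block 435 were called, 410 of them among the 759. The count was 1806 without the 8 libraries of extreme slope and 5318 by limma voom. The balance turned in these fits, with 1604 higher and 1772 lower with the GC slope, 753 and 1053 without the extreme libraries and 2522 and 2796 by voom.

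**Figure D3:**
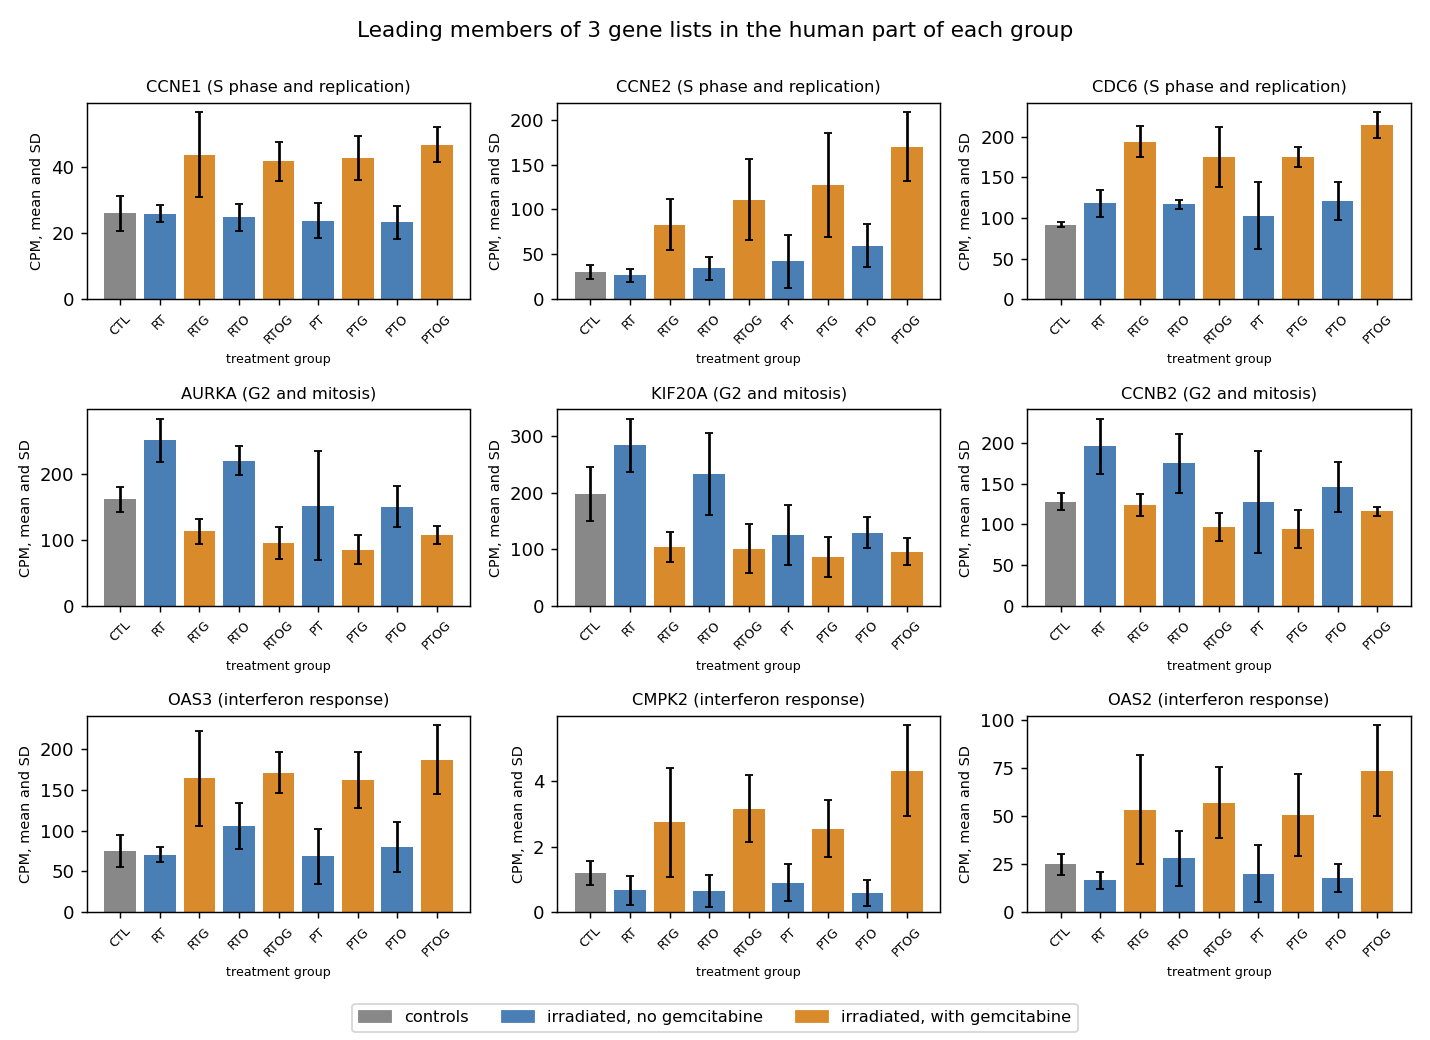
Mean CPM and SD of the leading members of the S phase, mitosis and interferon lists in the human part of each treatment group; grey marks controls, blue irradiated tumours without gemcitabine and orange those with it. CCNE2 means run from 26.5 CPM in RT to 170 in PTOG, and AURKA means from 252 in RT to 85.5 in PTG.

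Of 29 S phase and replication genes tested, 12 rose with gemcitabine, 0 fell and 17 did not pass. Adjusted over the list alone 14 rose, and the list median was 0.39 (camera adjusted p = 2.47e-22, adjusted p = 4.6e-05 with an estimated correlation). They included CCNE1 (log2 change 0.84 ± 0.09, edgeR adjusted p = 3.06e-08) and CDC6, which loads the replicative helicase (0.72 ± 0.09, edgeR adjusted p = 2.38e-07). Of 28 genes of G2 and mitosis, 14 fell and 14 did not pass, and 18 fell adjusted over the list alone. The median was -0.51 (camera adjusted p = 1.09e-15, adjusted p = 0.0421 with an estimated correlation), with AURKA at -0.92 ± 0.12, the kinesin KIF20A at -0.91 ± 0.15 and cyclin B2 (CCNB2) at -0.57 ± 0.11. Against CTL the mitosis list did not pass in RTG (median -0.01, camera adjusted p = 0.77), RTOG (median -0.13, camera adjusted p = 0.104) or PTOG (median 0.18, camera adjusted p = 0.779). Under the GC slope as a covariate the gemcitabine result of this list had an adjusted p = 0.14 with an estimated correlation. Of 31 interferon response genes, 14 rose and 17 did not pass, and 19 rose adjusted over the list alone (median 0.45, camera adjusted p = 6.88e-26, adjusted p = 0.000582 with an estimated correlation). CMPK2, a mitochondrial nucleotide kinase induced by interferon, rose by 2.16 ± 0.29 and OAS3 by 1.09 ± 0.14 (edgeR adjusted p = 1.7e-06 and 5.69e-07).

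Of 23 homologous recombination and Fanconi genes, 9 rose and 14 did not pass, and 10 rose adjusted over the list alone (median 0.36, camera adjusted p = 1.99e-13, adjusted p = 0.0209 with an estimated correlation). The exonuclease EXO1 rose by 0.75 ± 0.11, BRCA1 by 0.73 ± 0.11 and FANCI by 0.67 ± 0.11 (edgeR adjusted p between 7.85e-06 and 0.000115). Of 22 genes of gemcitabine transport and metabolism, 4 rose and 18 did not pass, and adjusted over the list alone 6 rose and 2 fell (median 0.12, camera adjusted p = 0.00378, adjusted p = 0.00753 with an estimated correlation, or 0.0679 with the GC slope as well). RRM2 and RRM1, the subunits of ribonucleotide reductase, rose by 0.89 ± 0.15 and 0.59 ± 0.12, and SAMHD1, which degrades deoxynucleotides, by 0.46 ± 0.11, though SAMHD1 had an adjusted p of 0.095 with the prefix block. Of 19 antigen presentation genes 2 rose, CD274 (PD-L1, log2 change 1.05 ± 0.17) and B2M (0.40 ± 0.10), and 17 did not pass. Adjusted over the list alone the count was again 2, and the list median was 0.21 (camera adjusted p = 0.00123, adjusted p = 0.28 with an estimated correlation). B2M had an adjusted p of 0.0906 with the prefix block. Of 16 histone genes, H1F0, a linker histone, fell (-0.83 ± 0.12, edgeR adjusted p = 5.27e-06) and 15 did not pass, also adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.00207, adjusted p = 0.0971 with an estimated correlation). None of 30 ribosomal protein genes passed, over all genes or adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.0101, adjusted p = 0.612 with an estimated correlation, and 0.749 with the mouse to human count ratio as a covariate).

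The other 9 lists did not pass for gemcitabine. Of 26 p53 targets 1 fell, PLK2 (log2 change -0.30, edgeR adjusted p = 0.0269, or 0.101 with the prefix block), and 25 did not pass; adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.453). The unfolded protein list (1 of 22 rose, camera adjusted p = 0.13) and apoptosis (1 rose and 1 fell of 24, 0.13) had the smallest values. Heat shock (0 of 12, 0.17), PARP, base excision and end joining (2 rose and 1 fell of 23, 0.3), cholesterol synthesis (3 rose of 20, 0.364) and hypoxia (0 of 24, 0.594) followed. For inflammatory and NF-kB genes 1 of 20 rose, the chemokine CXCL8 (log2 change 0.56 ± 0.13, camera adjusted p of the list 0.824), and EMT and TGF-beta genes had 1 rise and 1 fall of 22 (0.905). The cholesterol median of -0.03 and the inflammatory median of -0.08 were negative while their tests pointed up.

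**Figure D4:**
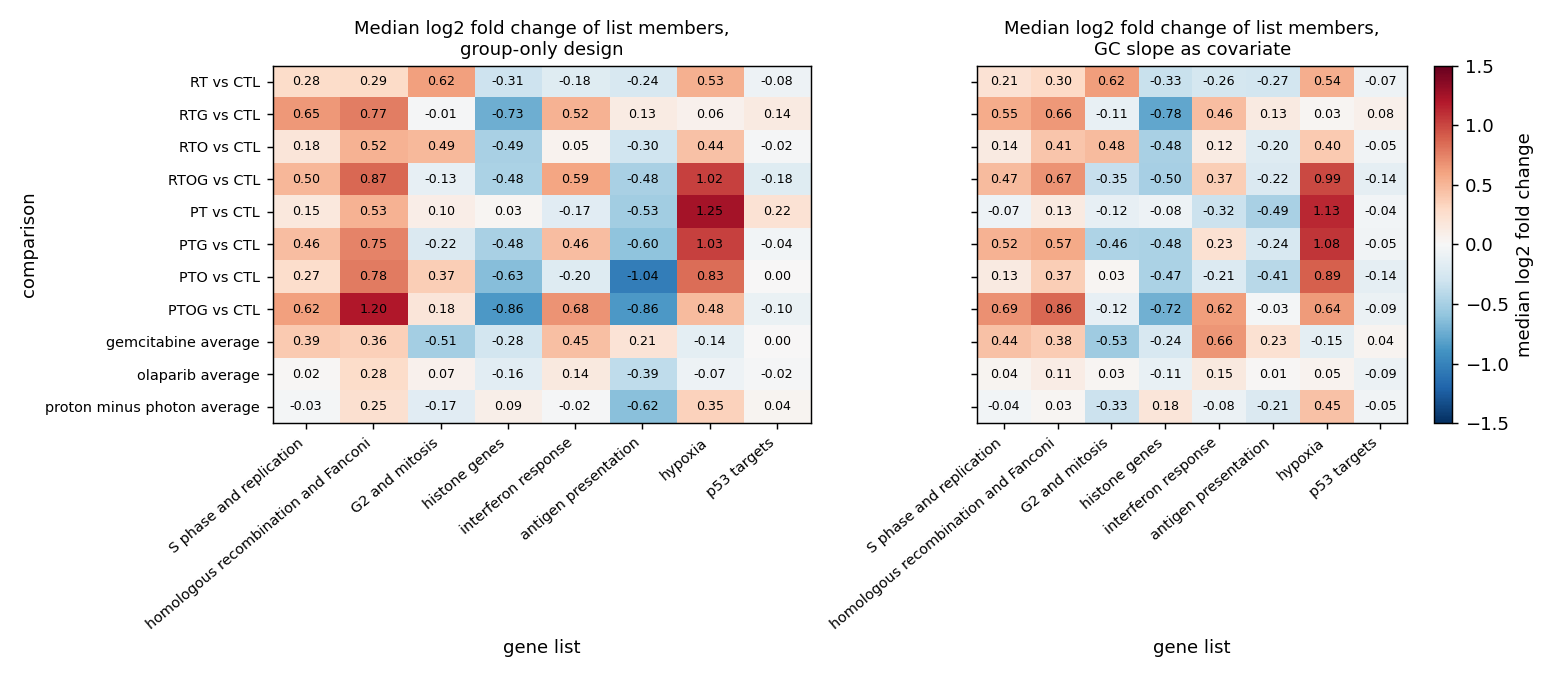
Median log2 change of the tested members of 8 human gene lists in the comparisons with CTL and in the 3 average contrasts, with the group-only design on the left and the GC slope as a covariate on the right. In the group-only design S phase genes had medians of 0.39 for gemcitabine and 0.02 for olaparib, and mitosis genes -0.51 for gemcitabine and 0.62 in RT.

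Photons alone left few single genes changed 24 h later, while mitosis genes stood higher as a group. NUSAP1, a spindle protein, had 303 ± 27.6 CPM in RT (n = 5) and 189 ± 39 in CTL (n = 5), and AURKA 252 ± 32.5 against 162 ± 19.2. CDKN1A, the p53 target that arrests the cell cycle, had a log2 change of -0.85 ± 0.49 and did not pass (edgeR adjusted p = 1). One gene was called, ANKRD33B (chromosome 5, 10564330 to 10657816, GRCh38), which stood at 30.7 ± 4.52 CPM in CTL and 16.8 ± 2.67 in RT and fell by 0.87 ± 0.16 (edgeR adjusted p = 0.0452).

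No list had a member called in RT against CTL, and 9 of 17 lists differed as a group from other genes. Of 28 genes of G2 and mitosis the median log2 change was 0.62 (camera adjusted p = 4.56e-23, adjusted p = 0.027 with an estimated correlation, and 0.0793 with both that and the GC slope as a covariate). CDC25C, the phosphatase that activates CDK1, had a log2 change of 0.68 ± 0.21, and the ubiquitin-conjugating enzyme UBE2C 0.64 ± 0.23. The 16 histone genes had a median of -0.31 (camera adjusted p = 1.04e-05, adjusted p = 0.027 with an estimated correlation, and 0.0793 with the GC slope as well), with HIST2H2BE at -0.67 ± 0.29. Homologous recombination genes (median 0.29, camera adjusted p = 4.2e-05, adjusted p = 0.213 with an estimated correlation), S phase genes (median 0.28, camera adjusted p = 0.000195, adjusted p = 0.12 with an estimated correlation), hypoxia genes (median 0.53, camera adjusted p = 0.000428, adjusted p = 0.418 with an estimated correlation) and PARP and base excision genes (median 0.13, camera adjusted p = 0.0194, adjusted p = 0.12 with an estimated correlation) stood higher. Interferon genes (median -0.18, camera adjusted p = 2.14e-05, adjusted p = 0.176 with an estimated correlation), antigen presentation genes (median -0.24, camera adjusted p = 0.000276, adjusted p = 0.214 with an estimated correlation) and inflammatory genes (median -0.27, camera adjusted p = 0.00202, adjusted p = 0.12 with an estimated correlation) stood lower. Among hypoxia genes, PDK1 stood at 50.3 ± 60.2 CPM in RT, and its log2 change of 1.08 became -0.047 without RT replicate 4. The p53 targets had a median of -0.08 (camera adjusted p = 0.349). Adjusted over the list alone, no member of any list passed. By edgeR 497 genes had an unadjusted p under 0.05, fewer than chance alone gives. DESeq2 called 11, voom 911 and the fit with the GC slope 32, with no call under RLE factors or without the expression filter. The edgeR count was 3 without RT replicate 5, 0 without each of RT replicates 1, 2 and 3, and 0 without each of CTL replicates 3, 4 and 5. Of 25 splits of the same tumours, 2 called at least 1 gene.

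With protons alone, 2 of 24 hypoxia genes rose and transcripts such as AQP1 fell against CTL. The hypoxia list as a group did not pass with an estimated correlation (adjusted p = 0.459). No CTL tumour shares a title prefix with a proton tumour, so protons and prefix cannot be told apart in any comparison of a proton group with CTL. AQP1, a water channel, stood at 145 ± 115 CPM in CTL (n = 5) and 4.39 ± 1.54 in PT (n = 5), and CD52, a short surface glycoprotein, at 13.2 ± 11.7 and 0.263 ± 0.194. EGLN1, the oxygen-sensing hydroxylase of the HIF pathway, stood at 87.8 ± 14.4 CPM in CTL and 196 ± 52.5 in PT. ARFGEF3 stood at 3.67 ± 1.65 and 28.7 ± 27. SAA1, an acute-phase protein, had 6.03 ± 5.59 CPM in CTL and 0.00959 ± 0.0214 in PT, too few counts for a fold change.

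For PT against CTL edgeR called 234 genes, 119 higher and 115 lower, against 3049 and 3092 by voom and 0 genes with only the groups compared. The median log2 change of all genes was 0.24, a shift the changes below include. ARFGEF3 rose by 2.97 ± 0.63 (edgeR adjusted p = 0.0143), TMEM74B by 4.27 ± 1.03 (0.0294), PPFIA4 by 3.22 ± 0.86 (0.0475), RIMKLA by 2.81 ± 0.62 (0.0192) and C4orf47 by 2.59 ± 0.60 (0.0247). CD52 changed by -5.57 ± 1.00 (0.0109), AQP1 by -5.04 ± 1.21 (0.0292), C6orf15 by -3.83 ± 0.99 (0.0414), PSORS1C1 by -2.65 ± 0.56 (0.0136), MYL2 by -2.65 ± 0.60 (0.0204) and the calcium-binding S100A2 by -2.41 ± 0.52 (0.0167), all edgeR adjusted p. Of 24 hypoxia genes, EGLN1 (1.16 ± 0.31) and INSIG2 (1.32 ± 0.36) rose and 22 did not pass, while 18 rose adjusted over the list alone (median 1.25, camera adjusted p = 4.82e-07, adjusted p = 0.459 with an estimated correlation). Of 19 antigen presentation genes PSME2, a proteasome activator subunit, fell (-1.04 ± 0.27, edgeR adjusted p = 0.0387) and 18 did not pass, with 7 falling adjusted over the list alone (median -0.53, camera adjusted p = 6.52e-06, adjusted p = 0.336 with an estimated correlation).

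No member passed in 5 further lists that differed as a group in PT. These were ribosomal proteins (median -0.10 but mean 0.004, camera adjusted p = 0.00577, adjusted p = 0.573 with an estimated correlation) and homologous recombination (median 0.53, camera adjusted p = 0.0208, adjusted p = 0.573 with an estimated correlation). The other 3 were interferon (median -0.17, camera adjusted p = 0.0225, adjusted p = 0.573 with an estimated correlation), cholesterol synthesis (median -0.04, camera adjusted p = 0.028, adjusted p = 0.336 with an estimated correlation) and inflammatory genes (median -0.05, camera adjusted p = 0.036, adjusted p = 0.459 with an estimated correlation). Fitted with the GC slope, the adjusted p was 0.864 for ribosomal proteins, 0.253 for homologous recombination and 0.0639 for inflammatory genes. CDKN1A had a log2 change of -1.76 ± 0.51 (edgeR adjusted p = 0.0624). The count of 234 genes in PT was 1553 with the GC slope, including all 234, 821 by DESeq2 and 1529 without the libraries of extreme slope. It was 0 without PT replicate 1, 97 without PT replicate 2, 439 without PT replicate 3, 2311 without PT replicate 4 and 152 without PT replicate 5, and 15, 26 and 34 without CTL replicates 1, 2 and 3. Another split of the same tumours called 6695 genes, so chance was not excluded for this count.

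Gemcitabine with photons raised replication and recombination genes against CTL. CDC6 stood at 92 ± 2.58 CPM in CTL (n = 5) and 194 ± 19.3 in RTG (n = 5), and EXO1 at 46.7 ± 4.68 and 97.1 ± 12.8. The smallest p in RTG belonged to RAB3B, a small GTPase of vesicle release (log2 change 2.15 ± 0.25), SEL1L3 (1.65 ± 0.19) and LINC00525 (1.95 ± 0.25), with edgeR adjusted p of 1.45e-06, 1.45e-06 and 5.78e-06. EdgeR called 430 genes, 279 higher and 151 lower. Of 29 S phase genes 9 rose and 20 did not pass (16 rose adjusted over the list alone, median 0.65, camera adjusted p = 3.74e-12, adjusted p = 0.0042 with an estimated correlation). Of 23 recombination genes 8 rose and 15 did not pass (11 adjusted over the list alone, median 0.77, camera adjusted p = 3.74e-12, adjusted p = 0.0379 with an estimated correlation). Of 16 histone genes 2 fell, also adjusted over the list alone (median -0.73, camera adjusted p = 2.9e-06, adjusted p = 0.02 with an estimated correlation). Of 31 interferon genes 2 rose, 5 adjusted over the list alone (median 0.52, camera adjusted p = 0.000323, adjusted p = 0.317 with an estimated correlation). Ribosomal proteins had no called member (median -0.30, camera adjusted p = 0.00301, adjusted p = 0.668 with an estimated correlation). The count was 2278 with the GC slope as a covariate, including all 430, 275 with the prefix block (251 shared), 646 by DESeq2 and 3614 by voom. It was 286, 259 and 282 without CTL replicates 1, 4 and 5 and 272 without RTG replicate 3.

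Olaparib with photons changed 3 genes against CTL, and 0 with only the groups compared in the fit. SEL1L3 rose by 1.22 ± 0.19 and RAB3B by 1.55 ± 0.24 (edgeR adjusted p = 0.000676 for both), and VXN fell by 1.15 on the log2 scale (SE 0.20, edgeR adjusted p = 0.00551). NUSAP1 stood at 302 ± 47.4 CPM in RTO (n = 6) and 189 ± 39 in CTL (n = 5). The split was 2 higher and 1 lower, and 2 higher and 2 lower under RLE factors. With no called member, 8 lists differed as a group, led by G2 and mitosis (3 rose adjusted over the list alone, median 0.49, camera adjusted p = 5.05e-11, adjusted p = 0.176 with an estimated correlation) and homologous recombination (6 rose adjusted over the list alone, median 0.52, camera adjusted p = 6.09e-10, adjusted p = 0.161 with an estimated correlation). The others were ribosomal proteins (median -0.38, camera adjusted p = 0.000221, adjusted p = 0.506 with an estimated correlation), histones (median -0.49, camera adjusted p = 0.000685, adjusted p = 0.161 with an estimated correlation), and antigen presentation (median -0.30, camera adjusted p = 0.00386, adjusted p = 0.441 with an estimated correlation). They also included hypoxia (median 0.44, camera adjusted p = 0.00478, adjusted p = 0.506 with an estimated correlation), inflammatory genes (median -0.30, camera adjusted p = 0.00679, adjusted p = 0.176 with an estimated correlation) and S phase (median 0.18, camera adjusted p = 0.0462, adjusted p = 0.442 with an estimated correlation). Hypoxia had an adjusted p of 0.15 with the prefix block and S phase 0.227 without the libraries of extreme slope. The count of 3 genes in RTO was 320 with the GC slope as a covariate, 14 with the prefix block, 32 by DESeq2, 5 without CTL replicate 4 and 9 without CTL replicate 5.

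In tumours given both drugs and photons, 10 of 23 recombination and 8 of 29 S phase genes rose against CTL, although neither list passed with an estimated correlation (adjusted p = 0.0561 for both). BRCA1, a recombination repair protein, stood at 72.9 ± 14.9 CPM in CTL (n = 5) and 184 ± 43.3 in RTOG (n = 5), a log2 change of 1.34 ± 0.22 (edgeR adjusted p = 0.000534). BMF, a pro-apoptotic BCL2 family member, stood at 16.5 ± 4.85 CPM in CTL and 2.29 ± 1.07 in RTOG (log2 change -2.85 ± 0.58, edgeR adjusted p = 0.00382). LAMP3, a lysosomal membrane protein, stood at 0.673 ± 0.279 and 3.29 ± 0.919 CPM (2.28 ± 0.35, edgeR adjusted p = 0.000223). H1F0 stood at 228 ± 58.1 and 101 ± 20.1 CPM (-1.17 ± 0.23, edgeR adjusted p = 0.00263). EdgeR called 475 genes, 288 higher and 187 lower, against 1096 and 1246 with the GC slope and 2707 and 3066 by voom.

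Among the largest rises in RTOG were LINC01629 (log2 change 3.23), VDR (2.72), ARFGEF3 (2.60), HSD17B6 (2.44), the lipoprotein receptor VLDLR (2.41), AKAP5 (2.29) and RHBDL3 (2.26), with edgeR adjusted p between 0.000534 and 0.0349. CD52 (-4.93), HIST1H1C (-2.68), MCHR1 (-2.39), LINC00592 (-2.38), PSORS1C1 (-2.35), the calcium-binding CALB2 (-2.23) and MYL2 (-2.13) fell, with edgeR adjusted p between 0.00228 and 0.0455; HIST1H1C, MCHR1, PSORS1C1 and MYL2 lost the call with the prefix block (0.114, 0.0607, 0.0698 and 0.0699). Of 23 recombination genes 10 rose and 13 did not pass (15 rose adjusted over the list alone, median 0.87, camera adjusted p = 6.8e-12, adjusted p = 0.0561 with an estimated correlation), EXO1 by 1.19 ± 0.22 and the helicase BLM by 1.24 ± 0.25. Of 29 S phase genes 8 rose and 21 did not pass (14 adjusted over the list alone, median 0.50, camera adjusted p = 2.66e-07, adjusted p = 0.0561 with an estimated correlation), CDC6 by 0.92 ± 0.17, CCNE2 by 1.86 ± 0.37 and RRM2 by 1.24 ± 0.30. Of 24 hypoxia genes P4HA1, a collagen prolyl hydroxylase subunit, rose (1.34 ± 0.36) and 23 did not pass, and 15 rose adjusted over the list alone (median 1.02, camera adjusted p = 2.66e-07, adjusted p = 0.386 with an estimated correlation).

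Of 31 interferon genes in RTOG, OAS3 rose (1.18 ± 0.27, edgeR adjusted p = 0.0124) and 30 did not pass, with 5 rising adjusted over the list alone (median 0.59, camera adjusted p = 0.000164, adjusted p = 0.386 with an estimated correlation). Of 16 histone genes 3 fell, also adjusted over the list alone (median -0.48, camera adjusted p = 0.000495, adjusted p = 0.103 with an estimated correlation). Ribosomal proteins (median -0.41, camera adjusted p = 0.00072, adjusted p = 0.6 with an estimated correlation) and antigen presentation (median -0.48, camera adjusted p = 0.0411, adjusted p = 0.525 with an estimated correlation) had no called member, and with the GC slope as a covariate their adjusted p was 0.364 and 0.286. The count of 475 genes in RTOG was 2342 with the GC slope, including all 475, 833 by DESeq2 and 776 with the mouse to human ratio as a covariate. It was 191, 223 and 249 without CTL replicates 1, 2 and 3, and 256 and 173 without RTOG replicates 2 and 5.

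In tumours given gemcitabine and protons, 10 of 23 recombination genes and 8 of 29 S phase genes rose against CTL, although neither list passed with an estimated correlation (adjusted p = 0.0963 for both). CCNE2 stood at 30.5 ± 7.75 CPM in CTL (n = 5) and 127 ± 57.9 in PTG (n = 5), and BRCA1 at 72.9 ± 14.9 and 164 ± 24.1. SEL1L3 rose by 1.60 ± 0.19, RAB3B by 1.73 ± 0.24, and the noncoding MIR4435-2HG fell by 1.30 on the log2 scale (SE 0.17), with edgeR adjusted p of 6.33e-06, 7.23e-05 and 1.51e-05. EdgeR called 722 genes, 425 higher and 297 lower, against 711 and 821 with only the groups compared. Of 23 recombination genes 10 rose and 13 did not pass (14 rose adjusted over the list alone, median 0.75, camera adjusted p = 3.15e-10, adjusted p = 0.0963 with an estimated correlation). Of 29 S phase genes 8 rose and 21 did not pass (14 adjusted over the list alone, median 0.46, camera adjusted p = 5.14e-06, adjusted p = 0.0963 with an estimated correlation). Of 24 hypoxia genes 4 rose and 20 did not pass (12 adjusted over the list alone, median 1.03, camera adjusted p = 1.69e-05, adjusted p = 0.493 with an estimated correlation). Of 31 interferon genes 1 rose (3 adjusted over the list alone, median 0.46, camera adjusted p = 0.00318, adjusted p = 0.493 with an estimated correlation). Of 28 mitosis genes 2 fell (4 adjusted over the list alone, median -0.22, camera adjusted p = 0.0146, adjusted p = 0.624 with an estimated correlation). Of 16 histone genes 2 fell (adjusted over the list alone 1 rose and 4 fell, median -0.48, camera adjusted p = 0.0175, adjusted p = 0.376 with an estimated correlation). With no called member, antigen presentation (median -0.60, camera adjusted p = 0.0175, adjusted p = 0.535 with an estimated correlation), inflammatory genes (median -0.40, camera adjusted p = 0.0235, adjusted p = 0.376 with an estimated correlation) and ribosomal proteins (median -0.50, camera adjusted p = 0.0235, adjusted p = 0.718 with an estimated correlation) stood lower. Under the GC slope their adjusted p was 0.108, 0.101 and 0.538, the last in the opposite direction. The count was 2728 with the GC slope, with 721 of the 722 shared, and 1111 by DESeq2. It was 321, 300 and 354 without CTL replicates 1, 2 and 3, and 479 and 312 without PTG replicates 3 and 5.

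With olaparib and protons, 14 of 23 recombination genes rose and 8 of 19 antigen presentation genes fell against CTL, and 4 rose and 3 fell with the GC slope as a covariate. Neither list passed with an estimated correlation (adjusted p = 0.503 for both). PSMB9, a subunit of the immunoproteasome, stood at 20.3 ± 9.76 CPM in CTL (n = 5) and 4.98 ± 3.09 in PTO (n = 5), and EXO1 at 46.7 ± 4.68 and 82.1 ± 20.9. RAB3B rose by 1.75 ± 0.24 and SEL1L3 by 1.31 ± 0.19, and CDC42BPG, a kinase, fell by 3.48 on the log2 scale (SE 0.48), with edgeR adjusted p of 0.000103, 0.000187 and 0.000103. EdgeR called 3737 genes, 2075 higher and 1662 lower, against 923 and 999 with the GC slope. Of 23 recombination genes 14 rose and 9 did not pass (adjusted over the list alone 18 rose and 1 fell, median 0.78, camera adjusted p = 8.9e-05, adjusted p = 0.503 with an estimated correlation). Of 19 antigen presentation genes 8 fell and 11 did not pass (10 adjusted over the list alone, median -1.04, camera adjusted p = 0.00105, adjusted p = 0.503 with an estimated correlation). Of 24 hypoxia genes 7 rose and 17 did not pass, also adjusted over the list alone (median 0.83, camera adjusted p = 0.00923, adjusted p = 0.696 with an estimated correlation). When the GC slope was added the median was 0.37 for recombination genes and -0.41 for antigen presentation genes. Ribosomal proteins had no called member (median -0.85, camera adjusted p = 0.00105, adjusted p = 0.696 with an estimated correlation), and the test turned direction with the GC slope as a covariate (adjusted p = 0.675). The GC slope averaged -0.491 in PTO against 0.371 in CTL, and with it as a covariate 1922 genes were called, of which 1047 were among the 3737 (28%). The count of 3737 was 2411, 1681, 2190 and 1956 without CTL replicates 1, 2, 3 and 5, and 880, 1812 and 1824 without PTO replicates 1, 3 and 4.

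With both drugs and protons, 16 of 23 recombination, 14 of 29 S phase and 10 of 31 interferon genes rose against CTL. None of these lists passed with an estimated correlation (adjusted p = 0.0847, 0.0847 and 0.396). REEP1, a membrane protein of the endoplasmic reticulum, stood at 3.33 ± 1.07 CPM in CTL (n = 5) and 23.5 ± 6.27 in PTOG (n = 4), and BRCA1 at 72.9 ± 14.9 and 227 ± 14.3. H1F0 stood at 228 ± 58.1 CPM in CTL and 56 ± 11.9 in PTOG, and AQP1 at 145 ± 115 and 1.51 ± 0.845. REEP1 rose by 2.82 ± 0.33 on the log2 scale (edgeR adjusted p = 1.16e-06), LAMP3 by 2.77 ± 0.36 (7.23e-06), the fatty acid elongase ELOVL7 by 2.75 ± 0.40 (2.43e-05), AKAP5 by 2.90 ± 0.46 (7.11e-05) and GPR137C by 2.77 ± 0.44 (7.11e-05). H1F0 changed by -2.03 ± 0.26 (4.5e-06), CD52 by -6.24 ± 1.15 (0.000432), AQP1 by -6.54 ± 1.45 (0.00247), C6orf15 by -4.67 (0.00567), the keratin KRT16 by -4.14 ± 1.04 (0.00736), the potassium channel KCNJ5 by -4.48 (0.00788), ANKRD2 by -4.15 ± 1.11 (0.0108) and CDSN by -4.76 ± 1.42 (0.0202). Among p53 targets, BAX fell (-2.70 ± 0.72, edgeR adjusted p = 0.0106) while SESN1 (0.99 ± 0.29) and FAS (1.18 ± 0.39) rose; with the GC slope as a covariate SESN1 and FAS did not pass (0.0717 and 0.179).

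EdgeR called 3056 genes for PTOG against CTL, 1698 higher and 1358 lower, against 3791 and 4424 with only the groups compared. Of 23 recombination genes 16 rose and 7 did not pass (17 adjusted over the list alone, median 1.20, camera adjusted p = 1.29e-10, adjusted p = 0.0847 with an estimated correlation), EXO1 by 1.61 ± 0.23 and BLM by 1.70 ± 0.26. Of 29 S phase genes 14 rose and 15 did not pass, also adjusted over the list alone (median 0.62, camera adjusted p = 4.92e-06, adjusted p = 0.0847 with an estimated correlation), CCNE2 by 2.48 ± 0.39 and CDC6 by 1.21 ± 0.18. Of 31 interferon genes 10 rose and 21 did not pass, also adjusted over the list alone (median 0.68, camera adjusted p = 0.00123, adjusted p = 0.396 with an estimated correlation), among them HERC5 (1.89 ± 0.37) and OAS3 (1.32 ± 0.29). Of 16 histone genes 6 fell and 10 did not pass (7 adjusted over the list alone, median -0.86, camera adjusted p = 0.00417, adjusted p = 0.239 with an estimated correlation). Of 30 ribosomal protein genes 7 fell and 23 did not pass (19 adjusted over the list alone, median -1.32, camera adjusted p = 7.26e-07, adjusted p = 0.508 with an estimated correlation), RPL37 by 1.70 on the log2 scale (edgeR adjusted p = 0.0199). With the GC slope 0 of them were called, and 3332 genes in all, 1806 of them among the 3056 (59.1%). The count of 3056 was 1996, 1612 and 1944 without CTL replicates 1, 2 and 3, and 1020 and 1582 without PTOG replicates 3 and 4.

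Averaged over its 4 pairs of groups, olaparib moved no human gene past the threshold. BRCA1 had a log2 change of 0.30 ± 0.11 (edgeR adjusted p = 0.129), the helicase BRIP1 0.43 ± 0.16 (0.129), HERC5 0.54 ± 0.17 (0.126) and BAX -1.20 ± 0.32 (0.126). In level, BRCA1 stood at 96.3 ± 13 CPM in RT (n = 5) and 116 ± 14.6 in RTO (n = 6). With no called member over all genes, ribosomal proteins stood lower (median -0.51, camera adjusted p = 2.22e-06, adjusted p = 0.748 with an estimated correlation), and recombination (median 0.28, camera adjusted p = 5.34e-06, adjusted p = 0.748 with an estimated correlation) and interferon genes (median 0.14, camera adjusted p = 0.00902, adjusted p = 0.748 with an estimated correlation) stood higher. The ribosomal list had an adjusted p of 0.133 with the GC slope as a covariate. The p53 target and histone lists did not pass, although 7 of 26 and 6 of 16 members fell adjusted over the list alone, and the S phase list had a median of 0.02, with POLA1 at 0.29 ± 0.11 (edgeR adjusted p = 0.129). The count of 0 was from edgeR, with 4705 genes at an unadjusted p under 0.05, and 243 genes were called by DESeq2 and 8731 by voom. It was 0 with the GC slope, 291 without the libraries of extreme slope, 1163 with the mouse to human ratio as a covariate and 55 without PT replicate 5.

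Averaged over the 4 matched pairs of treatments, 10 of 19 antigen presentation and 11 of 28 mitosis genes fell and 6 of 24 hypoxia genes rose with protons against photons. None of these lists passed with an estimated correlation (adjusted p = 0.811 for each). PLOD2, a collagen lysyl hydroxylase, stood at 0.728 ± 0.267 CPM in RTG (n = 5) and 15.2 ± 7.86 in PTG (n = 5), and at 2.34 ± 1.78 in CTL (n = 5). AQP1 stood at 102 ± 89.4 CPM in RT (n = 5) and 4.39 ± 1.54 in PT (n = 5), and CDSN, which codes for corneodesmosin, at 19.5 ± 19.5 and 0.681 ± 0.38. PSMB9 stood at 14.6 ± 6.36 CPM in RT and 5.44 ± 3.66 in PT. AMY2B, an amylase, stood at 2.07 ± 1.22 and 7.71 ± 4.02.

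EdgeR called 5018 genes for protons minus photons, 2623 higher and 2395 lower, against 3501 and 4070 without the libraries of extreme slope. PLOD2 rose by 2.10 ± 0.40 (edgeR adjusted p = 0.000642), AMY2B by 1.42 ± 0.23 (0.00016) and LHX1, a homeobox gene, by 1.43 ± 0.28 (0.000813), together with KCTD12 (1.48), UGT8 (1.47), EMB (1.39) and the antisense ROR1-AS1 (2.85), which is uncertain without the strand. CDSN changed by -3.50 ± 0.63 (0.000399), AQP1 by -3.47 ± 0.58 (0.000218), C6orf15 by -3.05 ± 0.49 (0.000171), PADI3 by -2.52 ± 0.46 (0.000475) and MEST by -2.34 ± 0.54 (0.00287), with KCNJ5 (-2.61), the aldehyde dehydrogenase ALDH3A1 (-2.56) and SAA1 also lower. Of 19 antigen presentation genes 10 fell, 2 rose and 7 did not pass (12 fell and 2 rose adjusted over the list alone, median -0.62, camera adjusted p = 0.0113, adjusted p = 0.811 with an estimated correlation), PSMB9 by -1.34 ± 0.28 and PSMB8 by -1.21 ± 0.26. Of 28 mitosis genes 11 fell and 17 did not pass, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0134, adjusted p = 0.811 with an estimated correlation), and CDC20 changed by -1.40 ± 0.29, or by -0.58 with the GC slope as a covariate (edgeR adjusted p = 0.0121). Of 24 hypoxia genes 6 rose and 18 did not pass, also adjusted over the list alone (median 0.35, camera adjusted p = 0.0433, adjusted p = 0.811 with an estimated correlation), EGLN1 by 0.67 ± 0.15 and BNIP3L by 0.82 ± 0.21.

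Of 26 p53 targets 5 rose and 5 fell between the beams (camera adjusted p = 0.731), with BAX (-1.41 ± 0.32) and CDKN1A (-1.11 ± 0.25) among the latter. When the GC slope was added 0 rose and 4 fell, with BAX at -0.69 and CDKN1A at -0.54 (edgeR adjusted p = 0.000152 and 0.0321). Ribosomal proteins stood lower (median -0.40, camera adjusted p = 0.0113, adjusted p = 0.811 with an estimated correlation) although the only member called, RPL7, rose (0.33, edgeR adjusted p = 0.0448), and the list turned direction with the GC slope (adjusted p = 0.161). The slope was lower in proton tumours, and with it as a covariate 2872 genes were called, of which 1642 were among the 5018 (32.7%); 3 antigen presentation genes then fell, 17 mitosis genes fell and 5 hypoxia genes rose. The prefix block could not be fitted because the beams share no prefix, so beam and prefix cannot be told apart for these 5018 genes. The G2 and hypoxia lists had adjusted p of 0.123 and 0.126 without the libraries of extreme slope, where 7571 genes were called, and the count was 8798 without PT replicate 4.

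Protons alone against photons alone changed 53 human genes, 21 higher and 32 lower, or 20 and 20 under RLE factors, 267 and 191 by DESeq2 and 0 genes with only the groups compared. CENPW, a centromere protein, changed by -1.67 ± 0.23 (edgeR adjusted p = 0.000177), the chaperonin subunit CCT5 by -0.95 ± 0.17 (0.00771) and F2R, a thrombin receptor, by 1.09 ± 0.19 (0.00771). Adding the GC slope as a covariate called 914 genes, including all 53, and DESeq2 called 458. The count was 1, 4, 4, 389 and 107 without RT replicates 1 to 5 and 1, 11, 152, 1909 and 86 without PT replicates 1 to 5, and another split of the tumours called 5052.

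Gemcitabine added to photons changed 58 genes against photons alone, 41 higher and 17 lower, but 1 with only the groups compared and 11 without the expression filter. The balance was 386 higher and 449 lower with the GC slope and 646 and 782 by voom. LINC00525 rose by 2.10 ± 0.25 (edgeR adjusted p = 2.76e-06), EXOC4, a subunit of the exocyst, changed by -0.91 ± 0.13 (0.000213) and the noncoding BISPR, next to BST2, rose by 1.96 ± 0.32 (0.00232). With the prefix block 33 genes were called, 32 of them shared, and 835 with the GC slope, including all 58. The count was 27, 28, 25, 28 and 34 without RT replicates 1 to 5 and 35, 17, 38 and 29 without RTG replicates 2 to 5. Gemcitabine added to protons changed 14 genes, 13 higher and 1 lower, against 55 and 89 by DESeq2, 356 and 818 by voom and 0 genes with only the groups compared. LINC00525 rose by 2.06 ± 0.25 (edgeR adjusted p = 4.96e-06), TCF19 by 1.21 ± 0.17 (6.68e-05) and DSN1, a kinetochore protein, by 0.91 ± 0.13 (0.000114). With the prefix block 4 of these were called, and 297 genes with the GC slope, including all 14. The count was 8, 23, 9, 9 and 74 without PT replicates 1 to 5 and 7, 9 and 26 without PTG replicates 2, 4 and 5, and another split of the tumours called 5975.

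No gene differed by edgeR between RTO and RT (353 at an unadjusted p under 0.05, 0 by DESeq2, 6554 by voom). The count was 0 also for PTO against PT (2541 unadjusted, 721 by DESeq2, 0 by voom), with 562 genes without PT replicate 2 and 438 without PT replicate 5. RTOG against RTG gave 0 (1414 unadjusted, 39 by DESeq2, 4903 by voom), with 7 genes without RTOG replicate 1. FOXN3, a forkhead factor, had a log2 change of 0.80 ± 0.18 there (edgeR adjusted p = 0.231, and 0.0332 with the GC slope, where 76 genes were called). PTOG against PTG gave 0 (378 unadjusted, 0 by DESeq2 and by voom). The test of gemcitabine by beam called 0 genes (508 unadjusted, 1 by DESeq2, 3 by voom). That of olaparib by beam called 0 (723 unadjusted, 0 by DESeq2 and by voom). Unadjusted counts of 353, 378, 508 and 723 were below what chance alone gives, and so no sign of change.

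Over all 17468 genes, the log2 changes of RT and PT against CTL correlated with r = 0.304 and a covariance of 0.0795. Genes are not independent, and both responses share the same 5 controls. In 1000 simulations of unchanged groups with shared controls the median r was 0.533 (95% range -0.237 to 0.893) with a mean covariance of 0.122. The GC slope varied less in CTL (SD 0.218) than within all groups (0.546), so these simulated values may be too high. With the controls split between the responses r averaged 0.038 (-0.147 to 0.228) with a covariance of 0.00957. After adjustment for the GC slope r was 0.457 with a covariance of 0.0931, against a simulated median r of 0.506 and covariance of 0.0581.

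Mouse genes differed from CTL in every irradiated group. The mouse gene ENSMUSG00000023067 rose by 3.07 ± 0.27 on the log2 scale in RT against CTL (edgeR adjusted p = 7.09e-10), and by 2.41 to 3.07 over the 8 irradiated groups. ENSMUSG00000020326 rose by 2.54 ± 0.31 in PT (edgeR adjusted p = 2.19e-06) and by 3.35 ± 0.32 in PTOG (1.08e-08). With gemcitabine ENSMUSG00000052305 changed by -5.37 ± 0.57 (edgeR adjusted p = 1.44e-07) and ENSMUSG00000073940 by -5.52 ± 0.71 (edgeR adjusted p = 2.59e-05). Of 15895 mouse genes edgeR called 30 in RT (25 higher, 5 lower), 48 in RTG (27 and 21), 63 in RTO (47 and 16), 679 in RTOG (373 and 306), 220 in PT (136 and 84), 338 in PTG (191 and 147), 2431 in PTO (1385 and 1046) and 1418 in PTOG (807 and 611). The gemcitabine average called 5 mouse genes (1 and 4, where another split called 61), the olaparib average 4 (2 and 2) and protons minus photons 3535 (1724 and 1811). For RT the balance turned to 45 higher and 59 lower by DESeq2, 85 and 139 by voom and 48 and 99 with only the groups compared. For RTG it turned to 135 and 173, 116 and 200, and 13 and 46 in the same fits, and to 100 and 174 with the GC slope. With the GC slope RTOG turned to 833 and 911, PTG to 493 and 524 and PTOG to 491 and 660, while by voom RTO turned to 459 and 572 and PTO to 3423 and 4021. Adding the GC slope as a covariate called 831 mouse genes in PTO, 508 of them among the 2431 (20.9%), and 1151 in PTOG, 610 of them among the 1418 (43%). For protons minus photons it called 813, 530 of them among the 3535 (15%). The 4 mouse genes of the olaparib average became 0 with the prefix block.

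The mouse counts moved with single tumours. Without 1 of CTL replicates 1, 2 and 3 the count was 40, 39 and 58 in PT, and 323, 303 and 307 in RTOG. In PT it was also 63, 1017 and 145 without PT replicates 1, 4 and 5, and in RTOG 452 without CTL replicate 5 and 427 and 341 without RTOG replicates 4 and 5. In RT it was 19 and 17 without CTL replicates 2 and 4. In RTG it was 27 and 25 without CTL replicates 4 and 5 and 28 and 23 without RTG replicates 2 and 5, and in RTO it was 39 and 39 without CTL replicates 1 and 2 and 41 and 39 without RTO replicates 3 and 5. In PTG it was 124, 115, 152 and 224 without CTL replicates 1, 2, 3 and 5 and 149, 222 and 82 without PTG replicates 3, 4 and 5. In PTO it was 1126, 958, 1108 and 1400 without the same CTL replicates and 844, 1127 and 1449 without PTO replicates 1, 3 and 4, and in PTOG 645, 574, 659 and 879 without those controls and 657, 321 and 435 without PTOG replicates 1, 3 and 4. For protons minus photons it was 2260 and 5412 without RTG replicates 4 and 5, 5933 without PT replicate 4 and 2280 without PTOG replicate 3. The olaparib average called 7 mouse genes without RT replicate 5 or RTO replicate 1. It called 2 without RT replicate 1, RTG replicates 1, 2 or 3, RTO replicate 3, RTOG replicate 4, PT replicate 3, PTG replicates 1 or 4, PTO replicate 4, or PTOG replicates 1 or 4.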

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

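The tests of the GC trend between libraries and behind the proton calls and gemcitabine lists were chosen only after those results were seen. The prefix and sample-split tests were set beforehand, as was the host ratio for gene counts.

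Among 12 measures in 9 groups (108 groups of values), 9 held a tumour far from the other tumours of its group, where chance alone marks about 1 in 20. RT replicate 4 stood low for 4 cell cycle genes on the log2 scale of CPM plus 1. It had 7.61 for AURKA (others 8 to 8.09), 7.68 for KIF20A (8.2 to 8.35), 6.5 for CDC6 (6.91 to 7.06) and 4.49 for CCNE1 (4.74 to 4.84). PTO replicate 5 stood low for AURKA at 6.66 (7.26 to 7.46), RTG replicate 5 for KIF20A at 5.87 (6.8 to 6.92) and RTG replicate 4 for CCNB2 at 6.66 (7.01 to 7.06). CCNE2 stood high in PTG replicate 5 at 7.85 (6.59 to 6.78) and in PTOG replicate 3 at 7.83 (7.22 to 7.29).

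The human libraries differed mainly along a trend with transcript GC content, and the first component carried 51.4% of their variance. If the trend arose in the library, mouse genes of the same tumour would share it. The first components of human and mouse genes correlated with Pearson r = 0.992 and Spearman rho = 0.994 over the 45 tumours (permutation p = 1e-04 for both, the smallest they can give), with r = 0.996 without the 2 most extreme tumours and 0.993 to 0.999 within prefixes. Treatment group accounted for a share of 0.265 of the variance of the slope (permutation p = 0.151), which argues against the 9 groups as the main source. The slope did differ between protons and photons by -0.447 (permutation p = 0.0156), so the beam, or the prefix that goes with it, stays open as a part of it. A bias of the whole library is therefore a candidate explanation, while RNA quality or handling behind it was not tested.

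How far the 5018 genes called between protons and photons rest on this trend stays open. With the GC slope as a covariate 32.7% of them were called in the same direction, which argues against the trend as the whole cause of the calls, although the remaining 1642 are fewer than the calls lost. The slope differs between the beams, so the covariate may also take up part of any beam effect, and without the libraries of extreme slope 7571 genes were called. The title prefix could account for the rest, because 0 prefixes hold both beams, and so beam and prefix cannot be told apart for any of these genes. The biological explanation, a different response to protons, stays open.

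The rise of S phase genes and fall of mitosis genes with gemcitabine may be a biological response, as a hypothesis found and tested on the same data. Under the GC slope as a covariate the larger camera adjusted p of both lists was 1.68e-16, with the prefix as a block 1.1e-18 and with the mouse to human ratio as a covariate 1.31e-21, each in the same directions, which argues against each as the whole cause. With an estimated correlation and the GC slope together the mitosis list had an adjusted p = 0.14, so its call depends on the correlation assumed between its genes. The test of the gemcitabine effect by beam called 0 genes by edgeR, but tests of single genes cannot show whether the lists moved alike. Mitosis medians against CTL were 0.62 (RT) and -0.01 (RTG), 0.10 (PT) and -0.22 (PTG).

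Other splits of the same tumours tested whether chance could give as many genes, with 25 splits per comparison, the real one included. The smallest share that these splits can give is 1 in 25, which was not adjusted over the comparisons. The splits argue against chance, for each comparison taken alone and unadjusted, where only 1 split, the real one, called as many genes. For human genes this held against CTL for RTG with 430 (highest other split 1), RTO with 3 (0) and RTOG with 475 (0). It also held against CTL for PTG with 722 (10), PTO with 3737 (27) and PTOG with 3056 (48). The others were the gemcitabine average with 759 (0), protons minus photons with 5018 (0) and RTG against RT with 58 (0). The same held for mouse genes in each irradiated group against CTL (30 to 2431 genes, highest other split 8) and for protons minus photons with 3535 (0). RTO had 0 genes with only the groups compared in the fit. The splits ignore the title prefix, and so they exclude no part played by it in any of these counts. No prefix holds both proton and CTL tumours, and all 5 RTG tumours are P3 while CTL and RT each hold 3 P3 and 2 P11 tumours. PT holds 4 P6 and 1 P10 tumours, and PTG 1 P6 and 4 P10. With the prefix as a block the counts were 275 for RTG and 477 for RTOG against CTL, 435 for the gemcitabine average and 33 for RTG against RT. For the mouse olaparib average only the real split called as many as 4 genes (highest other 1), but the count was 0 with the prefix as a block, so it is left open. Chance cannot be excluded for RT against CTL with 1 gene (2 splits, highest other 1), PT against CTL with 234 (2 splits, 6695), PT against RT with 53 (4 splits, 5052), PTG against PT with 14 (3 splits, 5975) or the mouse gemcitabine average with 5 (2 splits, 61). Where the real count was 0, all 25 splits gave as many. The highest others were 6092 for the olaparib average, 9493 for PTO against PT, 776 and 368 for the gemcitabine and olaparib effects by beam, 1 for RTOG against RTG and 0 for RTO against RT and PTOG against PTG. In human comparisons with PT some splits called several times the real count, and what sets those splits apart was not tested.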

How the results depend on the processing

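Fits with the GC slope, alone or with the prefix block, or without the libraries of extreme slope were chosen after the data were seen. All other settings were set beforehand for the gene counts.

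Comparisons named by 1 group are against CTL. The human counts in the main design were 1 for RT, 430 for RTG, 3 for RTO, 475 for RTOG, 234 for PT, 722 for PTG, 3737 for PTO and 3056 for PTOG. They were 759 for gemcitabine, 0 for olaparib, 5018 for protons minus photons, 53 for PT against RT, 58 for RTG against RT and 14 for PTG against PT, and 0 for the other 6 comparisons. The mouse counts were 30 for RT, 48 for RTG, 63 for RTO, 679 for RTOG, 220 for PT, 338 for PTG, 2431 for PTO, 1418 for PTOG, 5 for gemcitabine, 4 for olaparib and 3535 for protons minus photons. No paired analysis was possible because the replicate numbers only follow the order of the samples and mark no shared animal or day. Counts that moved by more than 1.5 times are given below for each setting; of the settings' effect on the counts, the cause was not tested unless stated.

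By DESeq2 the human count was 11 for RT, 646 for RTG, 32 for RTO, 833 for RTOG, 821 for PT, 1111 for PTG, 243 for olaparib, 458 for PT against RT, 175 for RTG against RT, 144 for PTG against PT, 721 for PTO against PT, 39 for RTOG against RTG and 1 for gemcitabine by beam. The mouse count was 104 for RT, 308 for RTG, 166 for RTO, 1404 for RTOG, 965 for PT, 845 for PTG, 2637 for PTOG, 42 for gemcitabine and 119 for olaparib. With RLE factors the human count was 0 for RT. Without the expression filter, where more genes were tested, the human count was 226 for RTG, 214 for RTOG, 50 for PT, 356 for PTG, 2058 for PTO, 1795 for PTOG, 7 for PT against RT, 11 for RTG against RT and 7 for PTG against PT, and 0 for RT. For mouse genes it was 19 for RT, 39 for RTO, 430 for RTOG, 112 for PT, 150 for PTG, 1332 for PTO and 594 for PTOG. By limma voom with quality weights the human count was 911 for RT, 3614 for RTG, 5057 for RTO, 5773 for RTOG, 6141 for PT, 4609 for PTG, 10303 for PTO, 10011 for PTOG, 5318 for gemcitabine, 8731 for olaparib, 10857 for protons minus photons, 7810 for PT against RT, 1428 for RTG against RT, 1174 for PTG against PT, 6554 for RTO against RT, 4903 for RTOG against RTG and 3 for gemcitabine by beam. The mouse count was 224 for RT, 316 for RTG, 1031 for RTO, 2518 for RTOG, 3712 for PT, 1890 for PTG, 7444 for PTO, 7398 for PTOG, 14 for gemcitabine, 3242 for olaparib and 7913 for protons minus photons.

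Under the GC slope as a covariate the human count was 32 for RT, 2278 for RTG, 320 for RTO, 2342 for RTOG, 1553 for PT, 2728 for PTG, 1922 for PTO, 3376 for gemcitabine, 2872 for protons minus photons, 914 for PT against RT, 835 for RTG against RT, 297 for PTG against PT and 76 for RTOG against RTG. Among mouse genes it was 133 for RT, 274 for RTG, 196 for RTO, 1744 for RTOG, 417 for PT, 1017 for PTG, 831 for PTO, 2 for olaparib and 813 for protons minus photons. Under the slope and the prefix block together the human count was 125 for RT, 1873 for RTG, 570 for RTO, 2555 for RTOG, 2513 for gemcitabine, 706 for RTG against RT and 93 for PTG against PT. The mouse count was 160 for RT, 121 for RTG, 296 for RTO, 1496 for RTOG and 0 for olaparib. Without the 8 libraries of extreme slope the human count was 3 for RT, 116 for RTO, 1529 for PT, 1806 for gemcitabine, 291 for olaparib, 7571 for protons minus photons and 1223 for PT against RT. For mouse genes it was 53 for RT, 26 for RTG, 124 for RTO, 776 for PT, 166 for PTG and 3 for gemcitabine.

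With only the groups compared in the fit, which leaves fewer samples, the human count was 236 for RTOG, 1532 for PTG, 6457 for PTO, 8215 for PTOG and 1 for RTG against RT, and 0 for RT, RTO, PT, PT against RT and PTG against PT. Among mouse genes it was 147 for RT, 30 for RTO, 443 for RTOG, 39 for PT, 4417 for PTO and 6035 for PTOG. With the prefix block alone the human count was 275 for RTG, 14 for RTO, 435 for gemcitabine, 33 for RTG against RT and 4 for PTG against PT. The mouse count was 0 for olaparib. With the mouse to human ratio as a covariate the human count was 5 for RTO, 776 for RTOG, 475 for PT, 1163 for olaparib, 197 for PT against RT and 22 for PTG against PT.

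Leaving out each tumour in turn, which leaves fewer samples, the human count ranged over 0 to 3 for RT, 259 to 380 for RTG, 2 to 9 for RTO, 173 to 494 for RTOG, 0 to 2311 for PT, 300 to 708 for PTG and 880 to 5528 for PTO. It ranged over 1020 to 3151 for PTOG, 0 to 55 for olaparib, 3431 to 8798 for protons minus photons, 1 to 1909 for PT against RT, 17 to 47 for RTG against RT, 7 to 74 for PTG against PT, 0 to 562 for PTO against PT and 0 to 7 for RTOG against RTG. The mouse count ranged over 17 to 26 for RT, 23 to 49 for RTG, 39 to 77 for RTO, 303 to 827 for RTOG, 39 to 1017 for PT, 82 to 394 for PTG, 844 to 3333 for PTO, 321 to 1487 for PTOG, 2 to 7 for olaparib and 2260 to 5933 for protons minus photons. The difference in mouse share, in percentage points, ranged over -1.99 to 2.75 for RT, -0.65 to 4.4 for RTO, -3.1 to 5.54 for RTOG, -2.07 to 3.22 for PT, -2.53 to 2.61 for PTO and -4.48 to 4.16 for RTOG against RTO, and none of these differences passed in any setting.

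The named values below reversed direction, and the cause was not tested for any of them. By limma voom the log2 change was -0.30 for CA9 in RT and -1.05 for RPS2 in PT, and RPS2 was -0.33 without the libraries of extreme slope. The range when each tumour was left out was -0.75 to 1.77 for RPS2 in PT, 0 to 5.26 for CA9 in RT and -0.047 to 1.31 for PDK1 in RT, all without RT or PT replicate 4 at the low end, and none of the 3 genes was called in the main design. In the fit with the GC slope, olaparib values turned positive for NFKB2 (0.001), RELB (0.036), MCM5 (0.013) and CDT1 (0.11), and RPL19 turned to 0.054 for protons minus photons. Together with the prefix block they were 0.082 for NFKB2, 0.063 for RELB, 0.098 for MCM5, 0.11 for CDT1 and 0.004 for CDC20. On the log2 ratio scale the mouse share in PT differed from CTL by -0.044. Under the GC slope the ribosomal protein list turned upward in PTG (adjusted p = 0.538), PTO (0.675) and protons minus photons (0.161), or 0.917, 0.988 and 0.866 with an estimated correlation.

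Of 69 list calls, 10 held with an estimated correlation and 59 did not, and with that and the GC slope together 6 held, 60 lost the call and 3 reversed, while all 69 held without the expression filter, 65 with the mouse to human ratio, 57 with the GC slope and 62 without the libraries of extreme slope. Of 40 list calls that could be fitted with the prefix block, 38 held. Of 264 gene values picked by the naming rule, 238 were on the same side of the threshold by DESeq2, 261 with RLE factors, 212 with the GC slope and 169 by voom. The correlation of the RT and PT responses was 0.217 over genes with a mean log2 CPM of at least 1 and 0.457 with the GC slope, while with split controls it ranged from -0.147 to 0.228, so its sign was not fixed. Whether sequencing depth limited the calls was not tested. At this sample size simulated changes of 2-fold were called for 18% of genes in RT against CTL and for 65% in the gemcitabine average.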

Other observations

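The contrast of all irradiated groups with CTL was chosen after seeing the data, as was its fit with the GC slope.

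Averaged over the 8 irradiated groups, 1144 human genes differed from CTL by edgeR, 551 higher and 593 lower, and 2760 with the GC slope as a covariate. Genes that fell included AQP1 (log2 change -3.54 ± 0.59, edgeR adjusted p = 0.000181), KCNJ5 (-2.70 ± 0.54, 0.00166) and MCHR1 (-2.41 ± 0.37, 6.23e-05). Genes that rose included LINC01629 (2.37 ± 0.55, 0.00567), ARFGEF3 (2.21 ± 0.53, 0.00792), SCN4B (1.81 ± 0.50, 0.0223) and RHBDL3 (1.67 ± 0.45, 0.0193). This average mixes irradiation with drugs and, for protons, the title prefix. Gemcitabine raised RHBDL3 and LINC01629, and AQP1 and KCNJ5 were lower with protons than photons. In the 4 photon groups, with the GC slope and the prefix block, 1905 genes differed from CTL. These groups include RTG and RTOG, are part of the 8 and share the 5 controls, so agreement is expected. In the photon fit AQP1 changed by -1.77, MCHR1 by -1.53 and RHBDL3 by 2.11 (edgeR adjusted p = 0.000431, 2.26e-05 and 1.07e-07).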
